A study of Mus musculus with 36 samples.

How the data were processed

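Native chromatin immunoprecipitation and sequencing of H2AK119ub1, a ubiquitin mark placed on histone H2A by Polycomb complexes, was profiled in 36 libraries from female mouse embryonic stem cells. Of these, 24 libraries were H2AK119ub1 and 12 were input DNA. The cells carry a doxycycline-inducible promoter at Xist, the gene of the RNA that silences the X chromosome in cis, on the 129S allele, and they are hybrid between the 129S and Castaneus strains. The genotypes were wild type (WT), clones with a deletion of the RNA recognition motifs of Spen (an RNA-binding protein of the Xist silencing pathway) and clones with a mutated SPOC domain of Spen. Cells were left uninduced or received doxycycline at 1 µg/mL for 3 h or 24 h. In the 24 h series, the genotypes and the WT replicates were each handled on a different occasion, so genotype and occasion cannot be separated. All libraries of the 3 h series were handled on a single day.

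The deposited files give, per 250 kb window of chromosome X, a normalized coverage signal that the authors summed per window. The scaling factor is not stated. Each library has a file of all reads and 2 files of reads assigned to genome 1 or genome 2. The values are not whole numbers and are never negative. According to the processing notes of the authors, Bowtie2 2.2.6, Picard and bedtools were used on mm10, with the role of each not stated. Which strain is genome 1 and which is genome 2 is not stated either. The files of all reads hold 685 windows of the whole chromosome, and the allelic files hold 414 windows that stop at Xist. The last allelic window, that of Xist, ended at 103500000 in the H2AK119ub1 libraries of WT replicates 1 and 2 of the 24 h series. In all other libraries it ended at 103483233. Drosophila chromatin was added to part of the 24 h libraries as a spike-in, which was not used in the deposited scaling nor here.

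For each window the log2 ratio of genome 2 over genome 1 signal was computed, after adding 1% of the median window to each. The ratio is formed within a library, so the unstated scaling cancels in it. The plan gave the ratio as genome 1 over genome 2, and the orientation was turned because the tests are two-sided. Windows were kept where both alleles averaged at least 10% of the median window over all libraries, which left 353 allelic windows. The same rule left 669 windows of the total signal, 267 of them past the end of the allelic files. The signal of chromosome X summed per library ran from 116006 to 277241 in H2AK119ub1 libraries and from 177468 to 189684 in inputs. If the smallest positive value of an allelic file stands for 1 fragment, the median window held about 451 fragments per allele in H2AK119ub1 libraries (range 294 to 1145) and 141 in inputs (range 121 to 247). That gives a counting error of 4.71% and 8.43% per allele, and it covers counting error only. The read numbers themselves are unknown.

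Changes between induced and uninduced libraries were tested per window with limma 3.58.1 in R 4.3.3, with a single fit of all groups per series, two-sided, and Benjamini-Hochberg (BH) adjustment at 0.05. Differences between genotypes are differences of these changes. They were tested on the ratio as it stands, called level, and after each library was centred on its median window, called pattern. Centring moved the median Spen minus WT difference of all windows from -0.16 to 0.17 on the log2 scale. Errors given with a window are standard errors (SE) from the fit. Shape measures per pair of libraries were compared with exact two-sided permutation tests on the absolute difference of means in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Plots were drawn with matplotlib 3.10.9. Windows along a chromosome are not independent replicates.

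The replicate numbers pair libraries, since a WT number stands for a shared occasion and a clone is a cell line. Across windows, the deviations of the uninduced and the induced library of a pair from their group means correlated at -0.01, -0.10 and 0.03 in WT, -0.00082 in Spen clones at 24 h, 0.12 in SPOC clones at 24 h, 0.16 in Spen clones at 3 h and 0.31 in SPOC clones at 3 h. A correlation across windows does not show an offset shared by all windows of a pair. The planned fit has no replicate block, and the fit with a replicate block is given beside a result wherever it changes a call or a count by more than 1.5 times.

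Gene positions came from RefSeq genes of GRCm38, the assembly of mm10, with 966 protein-coding genes on X, 580 of them in the allelic windows. The table gives no strand, so genes were placed by their midpoint and not by the start of transcription as planned. Before the data were examined, 6 gene lists were fixed: housekeeping genes, genes that escape X inactivation, developmental transcription factor genes, germline multicopy genes, long neural and muscle genes, and genes of the X-inactivation centre. Some windows stand in more than 1 list. Lists were tested with camera in limma, with an estimated correlation between windows, and with a preset correlation of 0.01 as an alternative. The rule for named windows was also fixed before the data were examined. It takes up to 5 windows per direction with the largest values among those past the threshold that moved the same way in every pair of libraries, at most 1 per 1 Mb. Not every window that the rule takes is named. It adds 2 to 4 genes per list with the largest differences, and always Xist, Kdm5c, Kdm6a, Eif2s3x and Ddx3x.

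Titles and file names of the 4 SPOC H2AK119ub1 libraries of the 24 h series give opposite induction states. The titles were used, and the values with the states exchanged stand beside them. The allelic values of these libraries argue against the titles, as given among the flagged results. Other alternatives were no pseudocount and a pseudocount of 10%, no filter and a filter at 50%, a fit of only the groups compared, windows of 1 Mb, a ratio corrected by the own input, division by the standard deviation over windows, and leaving out each replicate. The ratio corrected by input leaves out WT replicate 3, which has no input. Added after the data were seen were the comparisons with WT at 3 h, the share of a window covered by genes, leaving out windows within 20 Mb of Xist, the Spen minus WT pattern of the total signal, the classes of gene number and the counts over windows of the Btbd35f genes.

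The fits were tested on simulated data in which 200 of the 353 windows were changed. A change of 0.5 on the log2 scale was recovered in 93.0% of windows for WT, 76.9% for Spen clones at 24 h, 56.3% for the Spen minus WT level and 62.2% for Spen clones at 3 h. A change of 1 was recovered in at least 98.0%. Of the 153 unchanged windows, 2 to 9 were called.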

Results

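H2AK119ub1 was profiled in the 24 h series in 3 uninduced and 3 induced WT libraries, and in 2 clones per state of the Spen RRM deletion (C3 and D4) and of the SPOC mutant (E7 and H1). In the 3 h series there was 1 WT library per state, and 2 clones per state of the Spen RRM deletion (C3 and C4) and of the SPOC mutant (C11 and H1). Inputs were available for 2 pairs of each genotype in the 24 h series. Signal was read in 353 windows of 250 kb up to Xist for each allele, and in 669 windows of the whole chromosome X for all reads. The question put to these data is where along the chromosome the mark is laid down once Xist is switched on. It asks whether Spen, and its SPOC domain in particular, affects this. Xist RNA itself was not measured, so the values describe the mark and not the spread of the RNA. Positions are on mm10.

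In uninduced WT cells of the 24 h series the genome 2 share of the allelic signal was 52.0% ± 0.26 (SD, n = 3), and after 24 h of induction it was 68.5% ± 3.69 (SD, n = 3). The Spen clones went from 51.1% ± 0.06 to 63.5% ± 0.08 (SD, n = 2). In the SPOC clones the libraries titled uninduced stood at 65.1% ± 0.29 and those titled induced at 51.4% ± 0.25 (SD, n = 2). The inputs lay between 50.8% and 51.5%. At 3 h the WT share went from 53.7% to 73.8%, the Spen clones from 51.6% ± 4.10 to 61.5% ± 3.92, and the SPOC clones from 54.5% ± 0.58 to 68.4% ± 0.59 (SD, n = 2).

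**Figure D1:**
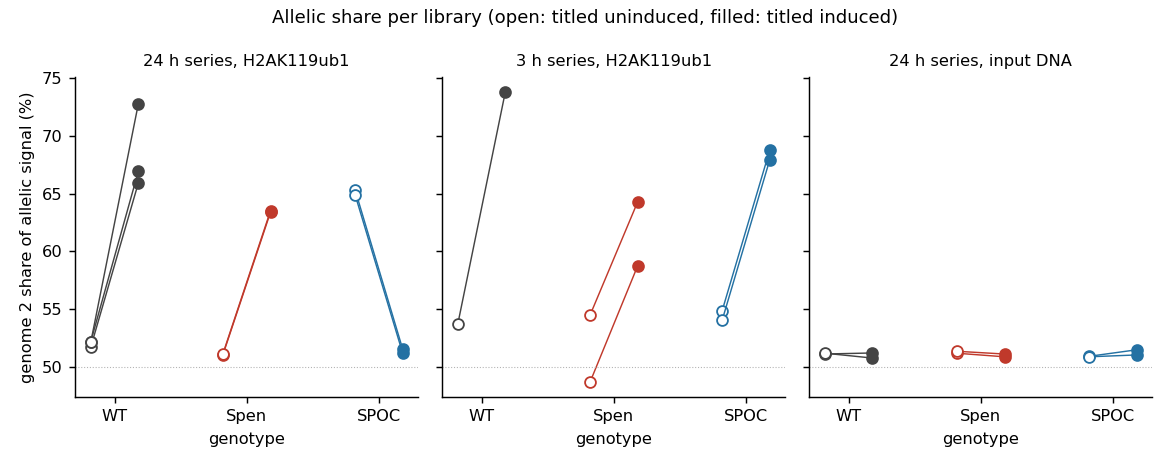
Genome 2 share of the allelic signal in percent (vertical axis) for each H2AK119ub1 library by genotype, in the 24 h and the 3 h series. Open points are libraries titled uninduced, filled points are libraries titled induced; WT rises from 52.0% to 68.5% at 24 h, while in both SPOC clones of that series the library titled uninduced is the higher.

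Induction for 24 h in WT cells asks where the mark is gained on the chromosome that carries the inducible Xist. The genome 2 to genome 1 ratio rose along nearly the whole measured part, with 334 of 353 windows higher and 0 lower in limma at BH 0.05 (334 at an unadjusted p under 0.05). The median log2 change per pair was 0.95 ± 0.24 (SD, n = 3), a fold of 1.93. On genome 2 itself the median change was 1.09 ± 0.19 and on genome 1 it was 0.12 ± 0.07 (SD, n = 3). Unlike the ratio, these values per allele rest on the deposited scaling. The window at X:85500001-85750000 with Tab3 and Gk had the largest change, 1.70 ± 0.14 (SE). Other large changes were in the window of Tsga8 within Dmd, the dystrophin gene (from 83250001, 1.64 ± 0.14). The window of Msn, from 96000001, changed by 1.58 ± 0.14, and that of Kif4, a kinesin gene, with Igbp1 and P2ry4, from 100500001, by 1.56 ± 0.14. The window of Xist itself, from 103250001, rose by 1.48 ± 0.14. Among genes that escape X inactivation, the window of Eif2s3x rose by 1.41 ± 0.14, that of Ddx3x by 1.02 ± 0.14 and that of Kdm6a by 0.41 ± 0.14 (adjusted p = 0.0044 for Kdm6a). Windows of all 6 lists rose without exception, namely 22 housekeeping, 5 escape, 7 developmental transcription factor, 12 germline multicopy, 8 long neural and muscle, and 2 X-inactivation centre windows. Housekeeping windows had a median of 1.30 against 0.94 in other windows, with adjusted p = 0.547 with an estimated correlation and 0.0007 with the preset one. Long neural and muscle windows had a median of 1.33, with adjusted p = 0.547 and 0.0058 in the same order. WT replicate 3 gained more (1.23) than replicates 1 and 2 (0.81 and 0.82).

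**Figure D2:**
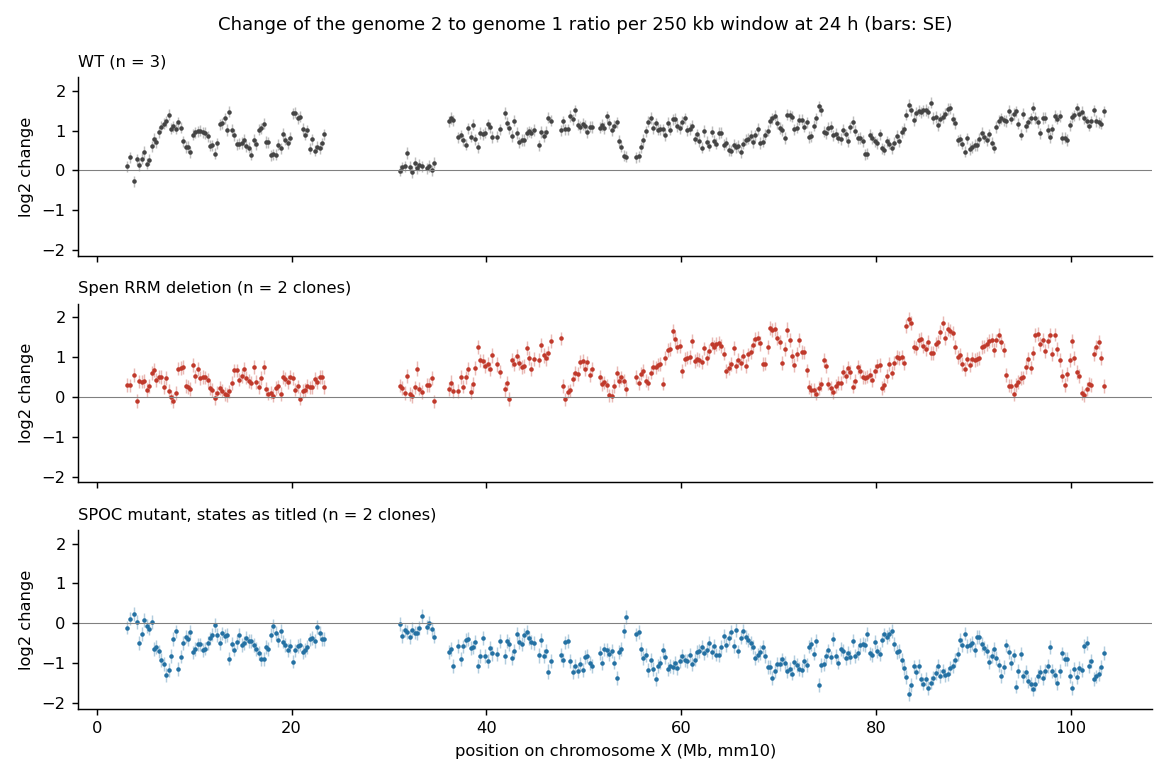
Log2 change of the genome 2 to genome 1 ratio (vertical axis) per 250 kb window against position on chromosome X in Mb, for WT (n = 3), Spen RRM deletion (n = 2 clones) and SPOC mutant (n = 2 clones, states as titled) at 24 h. Points are estimates and bars are SE; WT lies above 0 in 350 of 353 windows, and the SPOC values as titled lie below 0 except in 8 windows.

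Loss of the Spen RNA recognition motifs was compared with the uninduced state of the same clones at 24 h. The genome 2 to genome 1 ratio rose in 250 of 353 windows and fell in 0 in limma (260 at an unadjusted p under 0.05). Its median log2 change was 0.66 ± 0.02 (SD, n = 2), a fold of 1.58. On genome 2 the median change was 0.60 ± 0.01 and on genome 1 it was -0.02 ± 0.01 (SD, n = 2), values that rest on the deposited scaling. The largest gains lay in windows without housekeeping genes. These were the window of Tsga8 within Dmd (1.96 ± 0.18, SE), a pair within Il1rapl1, a long synaptic gene (from 86750001, 1.85 ± 0.17, and from 87250001, 1.70 ± 0.18), and windows with no protein-coding gene from 69000001 (1.72 ± 0.17) and 70750001 (1.69 ± 0.18). Of 22 housekeeping windows 3 rose, with a median of 0.20 against 0.71 in other windows; adjusted p was 0.538 with an estimated correlation and 9.6e-06 with the preset one. None of the 5 escape windows passed the threshold (median 0.07, adjusted p = 0.409 with an estimated correlation and 0.0075 with the preset one). Of the other lists, 3 of 7 developmental transcription factor, 10 of 12 germline multicopy, 6 of 8 long neural and muscle, and 1 of 2 X-inactivation centre windows rose. The Xist window had 0.28 ± 0.17 (adjusted p = 0.135), that of Eif2s3x 0.07 ± 0.17, that of Ddx3x 0.05 ± 0.17 and that of Kdm6a 0.03 ± 0.17.

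Whether the Spen deletion changes the distribution was tested as the difference of the 24 h changes between Spen clones and WT. After centring, Spen clones differed from WT in 188 of 353 windows, lower in 69 of them and higher in the rest, and without centring they were higher in 12 and lower in 83. Among the lowest differences were those in the window of Araf, a kinase gene, with Timp1, Elk1 and Uxt (X:20750001-21000000, -1.07 ± 0.12, adjusted p = 1.8e-05), that of Slc7a3 and Snx12 (from 101000001, -1.04 ± 0.13), that of Zfx and Eif2s3x (from 94000001, -1.02 ± 0.13) and that of Cask (from 13500001, -1.01 ± 0.13). In the Araf window WT changed by 1.35 ± 0.14 and the Spen clones by -0.04 ± 0.17. The largest positive differences lay in windows of Btbd35f10 and Btbd35f16 (X:3750001-4000000, 1.15 ± 0.23), of Mageb5 (from 91750001, 1.06 ± 0.15), of no protein-coding gene (from 97750001, 1.06 ± 0.15, and from 39000001, 0.99 ± 0.26) and of Btbd35f30 and Btbd35f5 (from 32750001, 0.98 ± 0.23). After subtraction of the own input and without WT replicate 3, the window from 3750001 had -0.07 and that from 39000001 had -1.23. The Xist window differed by -0.88 ± 0.16 (adjusted p = 0.0004), that of Ddx3x by -0.64 ± 0.14 (0.0013) and that of Kdm6a by -0.05 ± 0.15 (0.789). The Xist window ended further along in WT replicates 1 and 2 than in the Spen clones, so its difference compares unequal stretches. The count depended on scaling, as division by the standard deviation over windows left 31 higher and 34 lower. With the own input subtracted and WT replicate 3 left out, 2 changes at once, 20 were higher and 16 lower; without WT replicate 3 alone 168 windows differed. Without centring, the balance of 12 higher and 83 lower moved with single libraries: it was 51 and 89 without WT replicate 3, 5 and 89 without replicate 1, 3 and 70 without replicate 2, and 1 and 41 without Spen clone D4. Genotype and handling occasion cannot be told apart here.

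Windows of housekeeping genes were lower in Spen clones than in WT as a group. Of 22 windows, holding 27 of 37 listed genes, 19 were lower and 0 higher; adjusted over the list alone, 19 were lower and 1 higher. The median difference was -0.71 against 0.23 in other windows, with camera adjusted p = 0.0027 with an estimated correlation and 3.1e-12 with the preset one. Without centring the median was -1.04, with adjusted p = 0.135 with an estimated correlation. Examples are the windows of Nono and Med12 (-0.95 ± 0.14), of Usp9x, a deubiquitinase gene (-0.91 ± 0.14), and of Hcfc1 (-0.89 ± 0.12). The windows of Fmr1 (0.27 ± 0.12, adjusted p = 0.0719), Bcor (-0.11 ± 0.12) and Msn (-0.14 ± 0.18) did not pass the threshold. Of 5 escape windows 4 were lower and 0 higher over all windows and adjusted over the list alone, with a median of -0.64 against 0.18 and adjusted p = 0.0555 with an estimated correlation and 0.0028 with the preset one. Among these, the window of Utp14a differed by -0.58 ± 0.11.

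Of 7 developmental transcription factor windows 5 were lower and 1 higher, and 5 and 2 adjusted over the list alone (median -0.37; adjusted p = 0.17 with an estimated correlation and 0.025 with the preset one). The window of Gata1, a blood cell factor, differed by -0.88 ± 0.12 and that of Foxp3, the factor of regulatory T cells, by -0.71 ± 0.13. The higher window, of Nr0b1, had 0.32 ± 0.12 after centring and -0.01 without it. Of 12 germline multicopy windows 4 were higher and 0 lower after centring, also adjusted over the list alone (adjusted p = 0.585), among them Mageb1 (0.93 ± 0.12), Mageb2 (0.90 ± 0.16) and Magea4 (0.48 ± 0.13). Without centring 2 were higher and 2 lower. Of 8 long neural and muscle windows 3 were higher and 2 lower after centring, also adjusted over the list alone (adjusted p = 0.771). Without centring 0 were higher and 2 lower. Higher after centring only were Aff2 (0.65 ± 0.15), Il1rapl1 (0.49 ± 0.15) and Fgf13 (0.49 ± 0.14), and lower were Nlgn3, in the window of Nono, and Gpc3 (-0.75 ± 0.12). The medians of these last 2 lists changed sign with centring, from -0.13 to 0.19 for germline multicopy windows and from -0.15 to 0.18 for long neural and muscle windows; in the latter the median was positive after centring while the direction of camera was down. Of the 2 X-inactivation centre windows, that of Xist, Tsix and Jpx was lower, though its end differed between libraries. That of Nap1l2 had 0.14 ± 0.16 (adjusted p = 0.585 for the list, and 1 lower adjusted over the list alone).

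**Figure D3:**
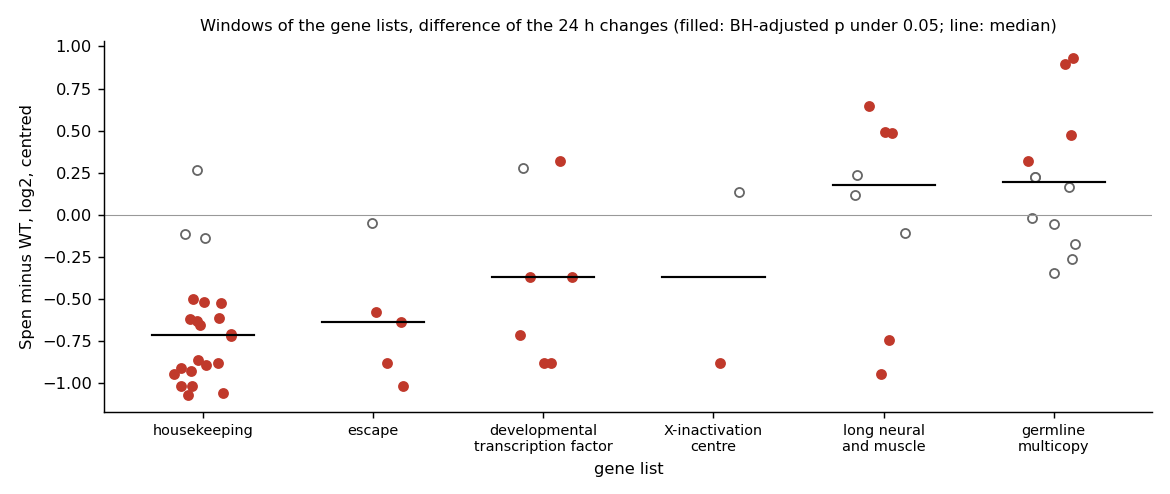
Difference of the 24 h changes, Spen minus WT after centring (log2, vertical axis), for the windows of the 6 gene lists. Each point is a window, filled where the BH-adjusted p is under 0.05, and lines are medians; the median of the 22 housekeeping windows is -0.71.

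Across windows, the change was related to the number of protein-coding genes in opposite directions in WT and Spen clones at 24 h. The Spearman rho per pair was 0.22 ± 0.05 in WT (SD, n = 3) and -0.34 ± 0.09 in Spen clones (SD, n = 2). With the share of a window covered by genes in place of their number, added after the data were seen, the rho was 0.58 ± 0.03 in WT and -0.05 ± 0.11 in Spen clones (0.03 in C3 and -0.13 in D4), so the opposite sign in Spen clones rests on gene number. The mean log2 change in the 125 windows without a gene was 0.84 ± 0.25 in WT and 0.87 ± 0.07 in Spen clones. In the 13 windows with 8 or more genes it was 1.08 ± 0.21 and 0.26 ± 0.10. Those classes of gene number were set after the data were seen and their means were not tested. The change followed the mean change of WT with a rho of 0.87 in WT pairs, each against the other two, and 0.25 ± 0.11 in Spen clones. The rho with distance from Xist was -0.36 ± 0.03 in WT and -0.47 ± 0.04 in Spen clones, and the interquartile range over windows was 0.50 ± 0.02 and 0.76 ± 0.05. Exact permutation tests between 3 and 2 pairs gave p = 0.1 for these 4 measures (BH-adjusted 0.125 over 5 comparisons) and p = 0.3 for the median change. The smallest p this design allows is 0.1.

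**Figure D4:**
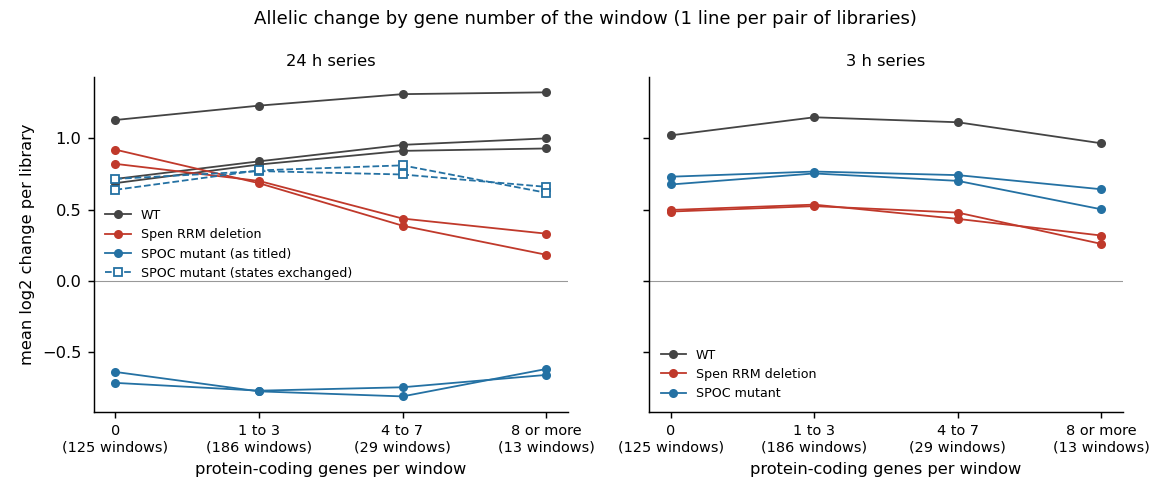
Mean log2 change of the genome 2 to genome 1 ratio (vertical axis) by number of protein-coding genes per window, 1 line per pair of libraries, in the 24 h and 3 h series. Dashed lines with open squares are SPOC clones with the states exchanged; at 24 h the Spen clones fall from 0.87 in windows with no gene to 0.26 in the 13 windows with 8 or more, and WT goes from 0.84 to 1.08.

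The SPOC mutant asks whether the C-terminal domain of Spen alone affects the mark. With the states as titled, the genome 2 to genome 1 ratio at 24 h was lower in 294 of 353 windows and higher in 0 in limma (296 at an unadjusted p under 0.05). Its median log2 change was -0.70 ± 0.01 (SD, n = 2). With the states exchanged, as the file names give them, 294 were higher with a median of 0.70. The largest values as titled were in the windows of Tsga8 (-1.76 ± 0.18), Msn (-1.64 ± 0.18), Eda, an ectoderm development gene (X:100000001-100250000, -1.62 ± 0.17), Fthl17a (from 85250001, -1.62 ± 0.17) and Klhl15 and Apoo (from 94250001, -1.59 ± 0.17), and each turned positive with the exchange. As titled, 19 of 22 housekeeping, 3 of 5 escape, 7 of 7 developmental transcription factor, 12 of 12 germline multicopy, 8 of 8 long neural and muscle, and 2 of 2 X-inactivation centre windows were lower. The Xist window had 0.75 with the states exchanged.

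Against WT, the SPOC change as titled was lower in 333 windows and higher in 1 without centring, and after centring it was higher in 115 and lower in 114. With the states exchanged, these counts were 0 higher and 18 lower without centring, and 5 higher and 12 lower after it. The median difference without centring was -1.66 as titled, which sets a rise in WT against a fall in SPOC clones. Exchanged, it was -0.17. As titled and centred, the highest were windows of the Btbd35f family (from 3750001, 2.19 ± 0.23, from 33250001, 1.77 ± 0.21, from 31000001, 1.69 ± 0.15, from 34000001, 1.59 ± 0.22, and from 32250001, 1.58 ± 0.22). Without centring these were 0.49, 0.08, -0.01, -0.10 and -0.12, and only the first passed the threshold, so the high values of the others come from centring. Among the lowest were the windows of Tsga8 (-1.71 ± 0.14), Msn (-1.52 ± 0.18), Tab3 and Gk (-1.49 ± 0.15) and Klhl15 (-1.37 ± 0.12). With the states exchanged, the highest that the rule takes was the window of Eda (0.55 ± 0.12, adjusted p = 0.018), followed by that of Asb12 and Zc4h2 (0.50 ± 0.11). Without centring these had 0.29 and 0.24 and neither passed. The largest value of any window after centring was 0.76, in a window that the rule does not take. The lowest were those of Usp9x (-0.73 ± 0.14, adjusted p = 0.011), of AA414768 (-0.67 ± 0.13), of Hcfc1 with L1cam and Naa10 (-0.61 ± 0.12), of Ebp and Suv39h1 (-0.59 ± 0.14) and of Araf (-0.56 ± 0.12). Exchanged, 7 of 22 housekeeping windows were lower and 0 higher (median -0.34 against 0.10, adjusted p = 0.009 with an estimated correlation), and 0 of 5 escape windows passed singly (median -0.35, adjusted p = 0.027). Exchanged, 1 long neural and muscle window was higher and 1 lower (median -0.03, adjusted p = 0.187), 1 of 7 developmental transcription factor windows was lower (adjusted p = 0.154), and 0 germline multicopy and 0 X-inactivation centre windows passed (adjusted p = 0.21 and 0.431). As titled, 8 housekeeping windows were lower and 2 higher (adjusted p = 0.564), 6 of 8 long neural and muscle windows were lower (adjusted p = 0.109 with an estimated correlation and 0.025 with the preset one), 2 developmental transcription factor windows and 2 X-inactivation centre windows were lower, and escape and germline multicopy windows went both ways, 2 and 2, and 4 and 4. In the exact permutation tests the 5 shape measures gave p = 0.1 as titled (BH-adjusted 0.1), with a difference of -1.66 in the median change, and p from 0.1 to 0.3 with the states exchanged. Exchanged, the rho with gene number was 0.09 ± 0.08 and the rho with the WT change 0.75 ± 0.02 (SD, n = 2).

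The direct comparison of the mutants asks whether they differ from each other. With the states as titled, Spen clones were higher than SPOC clones in 318 windows and lower in 0 without centring. That count rests on the titled direction, as the median change was 0.66 in Spen clones and -0.70 in SPOC clones as titled. With the states exchanged, the median Spen minus SPOC difference without centring was -0.0071. After centring they were higher in 116 windows and lower in 106. As titled and centred, the highest were the window of Tsga8 (2.35 ± 0.16), that of Vsig4 and Hsf3 (from 96250001, 1.70 ± 0.18), a window within Aff2 (from 69250001, 1.67 ± 0.17), a window within Il1rapl1 (1.66 ± 0.15) and that of Eda (1.65 ± 0.13). The lowest were windows of Btbd35f3 (from 4000001, -1.51 ± 0.18) and Btbd35f12 (from 33250001, -1.43 ± 0.23), of Bcor, a Polycomb-associated corepressor gene (-1.36 ± 0.13), of Gm14596 (from 54250001, -1.32 ± 0.24) and of Kdm6a (-1.27 ± 0.17). Without centring these 5 had -0.13, -0.06, 0.01, 0.05 and 0.10 and none passed the threshold, so their low values come from centring. With the states exchanged, 8 were higher and 23 lower without centring, and 61 were higher and 50 lower after it. Then among the lowest were the windows of Klhl15 and Apoo (-1.21 ± 0.13, adjusted p = 1.1e-05), Slc7a3 and Snx12 (-1.01 ± 0.15), Usp27x (from 7250001, -0.94 ± 0.14) and Pgrmc1 (from 36500001, -0.85 ± 0.17). The highest had no protein-coding gene (from 44000001, 1.08 ± 0.20, from 97750001, 1.03 ± 0.16, from 45500001, 0.95 ± 0.23, and from 66250001, 0.91 ± 0.15) or held Btbd35f10 (0.84 ± 0.25). The rho with gene number in Spen clones minus that in exchanged SPOC clones was -0.43, with exact permutation p = 0.333, the smallest that 2 against 2 pairs allow.

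At 3 h, the early stage of induction, all libraries came from a single day. The genome 2 to genome 1 ratio of Spen clones was higher in 155 windows and lower in 0. That of SPOC clones was higher in 263 and lower in 0. With a replicate block the Spen count was 272. Without SPOC clone C11 the SPOC count was 140, and without clone H1 it was 166. Median log2 changes were 0.44 ± 0.00 in Spen clones, 0.73 ± 0.05 in SPOC clones (SD, n = 2) and 1.10 in the WT pair, which has no replicate. The largest Spen changes were in a window within Dmd (from 84750001, 1.69 ± 0.21), and in those of Phka1 (from 102500001, 1.62 ± 0.21), Tsga8 (1.54 ± 0.21), Fthl17a (1.40 ± 0.21) and Eda (1.34 ± 0.21). For SPOC they were in the window within Dmd (1.82 ± 0.21), and in those of Hdac8, a deacetylase gene (from 102250001, 1.79 ± 0.21), Eda (1.62 ± 0.21), Fthl17a (1.56 ± 0.21) and Tsga8 (1.56 ± 0.21). In Spen clones 6 of 22 housekeeping, 1 of 5 escape, 4 of 7 developmental transcription factor, 5 of 12 germline multicopy, 5 of 8 long neural and muscle, and 2 of 2 X-inactivation centre windows rose. In SPOC clones these counts were 15, 2, 6, 11, 8 and 2. The rho with distance from Xist was -0.71 in WT, -0.69 in Spen and -0.77 in SPOC pairs, and the rho with gene number was 0.06, -0.03 and 0.01.

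The difference between Spen and SPOC clones at 3 h passed the threshold in 0 windows in limma without a replicate block. Clones C3 and C4 differed in level in both states, and that fit leaves this difference in its spread. Their median log2 ratios were 0.24 and -0.09 uninduced and 0.66 and 0.35 induced, while their median changes were both 0.44. At an unadjusted p under 0.05 there were 16 windows without centring (median -0.22) and 36 after it. With a replicate block 80 windows were lower in Spen clones without centring, and 5 differed after it, and without SPOC clone C11 1 window differed after centring. No window of the 6 lists passed after centring, with adjusted p from 0.457 to 0.654 for the lists; adjusted over the list alone, the 2 X-inactivation centre windows were higher and 0 in the other lists. Exact permutation tests of the 5 shape measures gave p = 0.333, the smallest possible with 2 against 2 pairs. Compared with the unreplicated WT pair, an addition after the data were seen that assumes WT to vary like the other groups, 48 windows were lower in Spen clones (median -0.60) and 1 in SPOC clones (median -0.37). After centring, 6 windows were higher and 3 lower in Spen clones, and 0 passed in SPOC clones (50 at an unadjusted p under 0.05). These counts moved with the replicate block, to 261 and 158 without centring and to 59 and 21 after it. The Spen count without centring was 1 with only the groups compared and 15 with no filter on low windows; after centring it was 36 and 0 in the same order, 15 with a pseudocount of 10%, and 0 after division by the standard deviation. The SPOC count without centring was 4 with only the groups compared, and 0 with that pseudocount, with windows kept at 50% and with windows of 1 Mb. Without Spen clone C3 or C4, the Spen count was 126 or 123 without centring and 0 after it, and without SPOC clone C11 or H1, the SPOC count was 0 without centring and 0 or 3 after it. With 1 WT library per state the spread of WT is borrowed from the mutants, so these counts do not establish that either mutant differs from WT at 3 h.

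Total signal covers the part of the chromosome past Xist, a part the allelic files used here do not reach. It rose at 24 h in 634 of 669 windows in WT (median log2 0.68) and in 458 in Spen clones (0.38), with 0 lower, and as titled it was lower in 529 windows in SPOC clones (-0.47; with the states exchanged 529 were higher). These counts rest on the deposited scaling; with each library centred on its median window they were 182 higher and 282 lower in WT, 159 and 337 in Spen clones, and 316 and 129 in SPOC clones as titled. The window of Kdm5c, an escape gene past Xist, had 0.88 in WT and 0.12 in Spen clones, a centred difference of -0.57 (adjusted p = 8.2e-05), the only 1 of 4 escape windows past Xist to pass the threshold (median -0.21). Over the whole chromosome, the centred Spen minus WT difference, added after the data were seen, was higher in 180 windows and lower in 189, and in the 267 windows past Xist it was higher in 107 and lower in 72. Past Xist, where the lists were counted and not tested as groups, 8 of 9 housekeeping windows were lower and 0 higher (median -0.79). Among them were Rbbp7, a chromatin factor gene (-0.96), Huwe1, a ubiquitin ligase gene (-0.95), and Pgk1, a glycolysis gene (-0.79). Of 9 long neural and muscle windows past Xist, 2 were higher and 2 lower, and of 5 germline multicopy windows 3 were higher and 0 lower.

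The inputs served as the background measured in the same way. They were tested in limma as the mean of the input changes of all genotypes, which can miss an imbalance in a single genotype. No window passed the threshold between induced and uninduced inputs, with 13 at an unadjusted p under 0.05. With a replicate block 1 passed, and 1 passed without the input of WT replicate 1 and 1 without that of SPOC clone E7. The median log2 change per pair of inputs was -0.01 ± 0.01 in WT, -0.02 ± 0.01 in Spen and 0.04 ± 0.02 in SPOC clones (SD, n = 2).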

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

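Tests chosen only after the result was seen are those of the exchanged titles, of a lowered mark in SPOC cells, of an imbalance in the DNA, of the handling occasions, of SPEN loss, of time, and of other splits of the WT libraries. The tests on few allelic reads and on the uninduced level were chosen before.

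Differences between genotypes at 24 h were singled out because the difference of the changes itself passed the threshold. They comprised 95 windows for Spen against WT without centring and 188 after centring. For SPOC against WT, states as titled, they comprised 334 and 229 windows, and for Spen against SPOC 318 and 222; with the states exchanged these were 18 and 17, and 31 and 111. For the WT counts the 6 libraries allow 10 splits, too few for a share under 0.05: 1 split, the real one, gave as many windows, with 334 against a highest other of 0 for the allelic ratio and 634 against 0 for the total signal.

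In the SPOC clones the median change as titled was -0.7049 at 24 h, while both clones of the 3 h series rose (0.77 and 0.70). The contrast was singled out because all clones of a series moved the opposite way from the other series, and the difference was not tested. The mark being lowered by induction is argued against, since the lowest median log2 ratio of the titled uninduced SPOC libraries was 0.769, above the highest of the 10 other uninduced libraries (0.2918). An exchange of the titles may account for it: the profile of titled uninduced minus titled induced followed the WT change with a rho of at least 0.7334 in both clones, and the file names give the exchanged states. Clone H1, measured in both series, had a genome 2 share of 54.1% uninduced at 3 h. Its 24 h libraries had 64.9% where titled uninduced and 51.2% where titled induced. For clone E7 these shares were 65.3% and 51.5%. With the ratios above, these values argue against the states as titled in both clones. The labels themselves do not state which of title and file name is right.

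In the Spen clones windows with many genes gained less than in WT, with a mean rho of the change with gene number of -0.3375 against a positive rho in every WT replicate (exact permutation p = 0.1, the smallest possible). Few allele-informative reads in such windows are argued against by the total signal, whose Spen minus WT difference had a rho of -0.4842 with gene number past Xist. Left open is an imbalance in the DNA, because the inputs had rho -0.128 in C3 and -0.0485 in D4, a first look that decided nothing, and subtracting them left -0.1513 in C3 and -0.327 in D4. Also open are the uninduced level, with rho nearest to 0 at -0.2007 in the middle group of windows by that level, too near the bound of -0.2 to exclude it, and the handling occasions, which cannot be told apart from genotype since each genotype of the 24 h series was handled on its own; the same-day 3 h difference between Spen and SPOC (rho -0.08466) does not bear on the comparison with WT. A loss of SPEN function stays open as well: the highest rho of a Spen clone was -0.2727 and the lowest of WT 0.1604, which restates the pattern and does not test its cause.

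The relation with gene number was near 0 in Spen clones at 3 h and negative at 24 h. In clone C3, measured at both times, the rho fell by 0.2555 from 3 h to 24 h, while the WT value differed by 0.1533 in the other direction. These values restate the contrast for 1 clone, so a change with time in Spen cells and a difference in handling between the series both stay open.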

How the results depend on the processing

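Tests added after the result was seen are the comparisons with WT at 3 h, the share of windows covered by genes, the windows within 20 Mb of Xist left out, and the total signal pattern. An alternative was counted as unchanged where a count of windows stayed within 1.5 times, or a shape measure kept its sign whatever its p. Windows and lists had to keep their direction and side of the threshold, and means per genotype had to move by less than their SD. Lists that passed in neither run were counted as unchanged even where their direction turned. Across results that answer a comparison, 346 alternatives were unchanged, 32 weaker, 20 stronger and 9 reversed. For single windows, lists and means per genotype 713 were unchanged, 49 weaker, 10 stronger, 41 moved and 25 reversed. The cause was not tested unless named. Beyond the counts given here, the replicate block moved no count of a comparison by more than 1.5 times and turned no direction. Depth limits single windows, with a counting error of 4.71% per allele at the median window.

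With windows of 1 Mb, fewer by construction, the counts were 88 for WT, 76 for Spen and 82 for SPOC at 24 h. Without centring they were 31 for Spen against WT, 88 for SPOC against WT and 89 for Spen against SPOC, and after centring 65, 68 and 67. At 3 h they were 48 for Spen, 75 for SPOC and 0 for SPOC against WT.

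With the own input subtracted and WT replicate 3 left out, the counts were 50 for Spen against WT without centring, and after centring 36 for Spen against WT, 104 for SPOC against WT and 130 for Spen against SPOC. In the Spen against WT pattern, the window from 3750001 had -0.068 and that from 39000001 had -1.23. Divided by the standard deviation, the Spen against WT pattern had 65 windows, the window from 34000001 had -0.023 for SPOC against WT, and that from 33250001 had 0.33 for Spen against SPOC.

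With the SPOC states exchanged, a reversal by construction, 294 windows differed at 24 h, and the windows from 83250001, 96000001, 100000001, 85250001 and 94250001 had 1.76, 1.64, 1.62, 1.62 and 1.59. Without centring the counts were 18 for SPOC against WT and 31 for Spen against SPOC. The SPOC against WT pattern had 17 windows, with -0.025 from 33250001, 0.38 from 83250001, 0.32 from 96000001, 0.040 from 85500001 and 0.36 from 94250001. The Spen against SPOC pattern had 111, with -0.16 from 100000001, 0.37 from 33250001, 0.0027 from 12000001, 0.42 from 54250001 and 0.029 from 18000001. The total signal had 529 windows, and the escape list against WT had adjusted p = 0.027, against 0.855 as titled and 0.814 to 0.853 in its other alternatives. SPOC minus WT was -0.14 for the rho with distance. Spen minus SPOC was -0.044 for the median change, 0.026 for the rho with distance and -0.49 for the rho with the WT change. The SPOC means were 0.70, -0.50, 0.088 and 0.75 for median change and rho with distance, gene number and WT change.

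With the share of windows covered by genes in place of gene number, the rho of Spen minus SPOC at 24 h was 0.34 with the SPOC states as titled and -0.45 with them exchanged, and the mean of Spen at 3 h was 0.27. With the replicate block, counts were 272 for Spen at 3 h, 80 and 5 for Spen against SPOC at 3 h without and after centring, 1 for the inputs, 261 and 59 for Spen against WT at 3 h, and 158 and 21 for SPOC against WT at 3 h. Without a filter, Spen against SPOC at 3 h without centring had 1, and Spen against WT at 3 h had 15 and 0. With only the groups compared, Spen against WT at 3 h had 1 and 36 and SPOC against WT 4. With a pseudocount of 10%, the Spen against WT pattern at 3 h had 15 and SPOC against WT had 0 without centring, as with the filter at 50%. Division by the standard deviation left 0 in the Spen against WT pattern at 3 h. With the preset correlation, camera adjusted p was 0.025 for developmental transcription factor genes and 0.0028 for escape genes in the Spen against WT pattern. With the estimated correlation neither list passed (0.17 and 0.0555).

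Leaving out a replicate gave 42 to 140 for Spen against WT without centring (42 without clone D4), 140 to 166 for SPOC at 3 h, 0 to 1 for the Spen against SPOC pattern at 3 h and for the inputs, 123 to 126 and 0 to 0 for Spen against WT at 3 h without and after centring, and 0 to 0 and 0 to 3 for SPOC against WT at 3 h. A lone sample left in a group is assumed to vary like the others.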

Other observations

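Windows of the Btbd35f genes, a multicopy family expressed in the male germline, were grouped after their values were seen and not tested against other windows. The 18 measured windows with 25 of these genes had a median log2 change of 0.10 in WT at 24 h, from -0.27 to 0.60, with 3 higher and 0 lower. In Spen clones the median was 0.29, with 6 higher and 0 lower, and in SPOC clones as titled it was -0.10, with 0 higher and 1 lower, and with the states exchanged 0.10, with 1 higher and 0 lower.

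The window of Kdm6a, a histone demethylase gene that escapes X inactivation, had 0.41 ± 0.14 in WT at 24 h, and that of Bcor had 0.41 ± 0.14, against a median of 0.96 over all windows. In total signal past Xist, the centred Spen minus WT difference was 0.45 in the window of Pou3f4 (adjusted p = 4.5e-05) and -0.80 in that of Klf8 (adjusted p = 3.8e-06), both developmental transcription factor genes; of the 4 windows of that list past Xist, 2 were higher and 1 lower. It was 0.37 in the window of Pcdh11x and 0.36 in that of Il1rapl2, long neural genes of a list with 2 higher and 2 lower. Of the 2 X-inactivation centre windows past Xist 1 was lower, that of Rlim, which encodes an activator of Xist (-0.39).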
